A study of Mus musculus with 10 samples.

How the data were processed

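DNA of all microbes in mouse intestinal contents was extracted with a kit and made into shotgun metagenomic libraries, per the labels' protocols. There were 10 libraries, 5 with the label Young and 5 with the label Young+B.ca. The text that describes the series speaks of young and aged mice, while these labels hold only Young and Young+B.ca, so the groups follow the labels. The authors deposited 1 table of 8006 species names with 1 column per library, in which each value is the fraction of the library given to that species, per the file headers and the column sums of 1. The read filter, the removal of mouse reads, the classifier, its database and their versions are not given in the sources used here. Reads of related species can be shared between their names by a classifier, so single species names, above all within Bacteroides or Blautia, are less certain than genera and lists. Depth per library is unknown and no counting interval was given. The smallest listed share, from 0.000109% to 0.000357%, differed between libraries, which bears on values near it and on the number of species listed.

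The groups, tests, taxon lists, naming rule and most alternatives were fixed before the data were examined. Fractions are printed as percent. Species above 0 in at least 5 of the 10 libraries were tested, 5708 in all, as log2(share + pseudocount), with a pseudocount of 5.45e-05%, which is the smallest share above 0 divided by 2. A fold change is on this scale. For scarce species it depends on the pseudocount and on libraries in which the species is not listed. It can then differ in size or sign from the ratio of the mean shares. Bradyrhizobium canariense, above 0 in 9 libraries, had a log2 fold change of 0.570 with means of 0.00209% in Young and 0.00187% in Young+B.ca. limma 3.58.1 in R 4.3.3 gave log2 fold changes of Young+B.ca over Young, standard errors and two-sided p-values with Benjamini-Hochberg adjustment at 0.05. Shares were summed by the first word of the species name to 2203 genera, of which 1947 were tested in the same way. Names in the table carry no lineage, so 85 genera with a mean share of at least 0.05% were assigned to phyla by hand after the names had been seen, and phyla with a mean share of at least 0.1% were tested. Shares of phyla and lists, diversity and richness were compared with two-sided exact permutation tests over all assignments of 5 libraries to each group, whose smallest p is 0.00794. Values were adjusted over 8 phyla and over 19 lists. A permutational test of group separation on Bray-Curtis dissimilarities ran over all splits into 2 groups of 5. Lists with at least 5 tested members also entered limma's camera, with its preset correlation and with an estimated one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

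The lists covered the B.ca name match, Bacteroides with Phocaeicola, Parabacteroides and Alistipes, Muribaculaceae, Prevotella, Lactobacillaceae, Bifidobacterium, Akkermansia, butyrate producers, Lachnospiraceae, Oscillospiraceae, Erysipelotrichia, segmented filamentous bacteria, sulfate reducers, Enterobacteriaceae, Helicobacter with Campylobacter, enterococci with staphylococci and streptococci, reagent contaminants and fungi. Members were matched to genus or species names written down beforehand, so a list that bears the name of a family or class does not hold all of it, and some species stand in more than 1 list, as Bacteroides caecimuris does. Lists of archaea, viruses, and host and diet need a lineage or other names and matched 0 names, and lists of glutamate and butyrate genes were not used because the table holds no functions. Species were named by a fixed rule: the 10 most abundant, the 10 largest rises and 10 largest falls among species past the threshold with a mean share of at least 0.01%, up to 5 B.ca name matches and up to 3 most abundant members of each list. Genera followed the same rule with 5 in place of 10.

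The species test was tested on simulated data with the real mean and spread of each species. Each species was drawn on its own from a normal distribution, so species did not vary together and shares did not add up to 1. Real species did vary together, with an estimated correlation of 0.699 within the Lachnospiraceae list. The simulated percentages of false calls may therefore not hold for the real libraries. Changes were planted in 200 of 5708 species, 200 of 1947 genera and 104 of the 314 species of at least 0.01%, as many up as down. Recovery depends on these numbers, which need not be those of the real libraries. Among 5708 species the test recovered 0% of changes of 1 on the log2 scale and 29.0% of changes of 2, with 0 false calls. Among 1947 genera it recovered 30.0% and 75.0%, with 7.08% of calls false, and among the 314 species of at least 0.01% it recovered 50.0% and 94.2%, with 5.06% of calls false. A species that did not pass can therefore still have changed. No library pair held identical values, and correlations of log2 shares lay between 0.666 and 0.748 within Young and between 0.666 and 0.766 within Young+B.ca. Alternatives were the centred log ratio, other filters and pseudocounts, other distances, ranks and denominators, the replicate number as a block, and each library left out in turn. Alternatives meant for counts were not used, since the values are fractions. The bounds for reading the tests of shared reads and of complementary shares were tightened after their values had been seen. This left 2 more explanations open. The test of reads given to other Bacteroidota genera was replaced too, which left such reads open as part of the rise.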

Results

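Microbial DNA from the intestinal contents of mice was surveyed by shotgun metagenomic sequencing, in which all DNA of a sample is sequenced and assigned to species. The libraries fell into 2 groups of 5, Young (n = 5) and Young+B.ca (n = 5). The labels do not spell out B.ca or say whether, how or when anything was given. The series title names glutamic acid under the control of gut microbes and the quality of oocytes at advanced reproductive age. The comparison made here asks how the intestinal community of the Young+B.ca libraries differed from that of the Young libraries. The deposited table gave each of 8006 species names as a fraction of its library. Sequencing depth is unknown, because the fractions of every library add up to 1. Between 3858 and 5870 species were listed per Young library and between 5592 and 6056 per Young+B.ca library. The smallest share listed lay between 0.000203% and 0.000357% in the Young libraries and between 0.000109% and 0.000221% in the Young+B.ca libraries. Helicobacter typhlonius, a spiral bacterium of the mouse lower bowel, was the most abundant species in all 10 libraries, at 7.33% to 38.3%. The labels do not say that the libraries of a group came from separate animals or cages, so p-values measure the spread between these libraries only.

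Species whose names fit the label B.ca, taken as a genus beginning with B and an epithet beginning with ca, were examined first. Their summed share rose from 0.604% ± 0.279 (SD, n = 5) in Young to 3.15% ± 1.11 (SD, n = 5) in Young+B.ca, which is 5.22 times as much. All 5 Young+B.ca libraries lay above all 5 Young libraries (exact permutation p = 0.00794, adjusted p = 0.0215 over 19 lists). Bacteroides caecimuris, a Bacteroides species described from the mouse caecum, made up 91.8% of the sum. It rose from 0.529% ± 0.239 to 2.92% ± 1.04, a log2 fold change of 2.49 (SE 0.47, adjusted p = 0.0237). Bacteroides caccae had 0.0665% ± 0.0406 in Young and 0.223% ± 0.0913 in Young+B.ca and did not pass (adjusted p = 0.0727), though it did among species of at least 0.01% tested alone (adjusted p = 0.00657). Bifidobacterium catenulatum, a scarce member of the same name match, fell from 0.00317% ± 0.000693 to 0.00128% ± 0.000232 (adjusted p = 0.0427). Of 7 name matches tested, 1 was higher, 1 was lower and 5 did not pass, against 3 higher and 1 lower when adjusted over the list alone. Bradyrhizobium canariense and Bergeyella cardium had adjusted p-values of 0.792 and 0.756. Brevibacterium casei, named after its values were seen, lay higher in all 5 Young+B.ca libraries than in any Young library, at 0.00226% ± 0.000470 against 0.000551% ± 0.000574 (exact p = 0.00794), and did not pass in limma (adjusted p = 0.108). The call of Bacteroides caecimuris was lost without Young 1 and without Young+B.ca 1, 2, 4 or 5 (adjusted p from 0.0576 to 0.0689), with its log2 fold change between 2.34 and 2.44 in those fits, and that of Bifidobacterium catenulatum was lost on leaving out any 1 of 9 libraries (adjusted p up to 0.0998). The label itself does not tell which of these species, if any, was meant.

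At the level of phyla, Bacteroidota rose and Bacillota fell. Bacteroidota, Gram-negative anaerobes that break down polysaccharides, made up 14.5% ± 4.79 (SD, n = 5) of the Young libraries and 38.8% ± 9.45 (SD, n = 5) of the Young+B.ca libraries, or 2.67 times as much. Bacillota, which hold the clostridia and lactic acid bacteria, went from 42.3% ± 10.2 to 20.5% ± 3.90. The 2 groups did not overlap in either phylum (exact permutation p = 0.00794 for each, adjusted p = 0.0317 over 8 phyla). Campylobacterota, nearly all of it Helicobacter, had 30.5% ± 14.1 in Young and 28.4% ± 8.50 in Young+B.ca (exact p = 0.738). Deferribacterota, which here is Mucispirillum, a dweller of the mucus layer, had 3.27% ± 2.04 and 3.45% ± 2.19 (exact p = 0.889). Verrucomicrobiota, here Akkermansia, had 0.179% ± 0.268 and 0.866% ± 0.768 (exact p = 0.0556, adjusted p = 0.148). Thermodesulfobacteriota, here Desulfovibrio alone since genera under 0.05% were given no phylum, had 0.102% ± 0.0213 and 0.220% ± 0.129 (exact p = 0.143). Desulfobulbus, a scarcer genus, is therefore in no phylum sum. Pseudomonadota had 0.672% ± 0.108 and 0.726% ± 0.187, and Actinomycetota 0.530% ± 0.133 and 0.485% ± 0.0531, with exact p-values of 0.579 and 0.603. Genera given no phylum held 7.88% ± 1.33 of the Young and 6.63% ± 0.674 of the Young+B.ca libraries. An exact p of 0.00794 is the smallest that permuting the 10 libraries can give. With any 1 library left out, the adjusted p of both phyla was 0.0635, with unadjusted exact p-values from 0.00794 to 0.0159, and neither call passed.

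**Figure D1:**
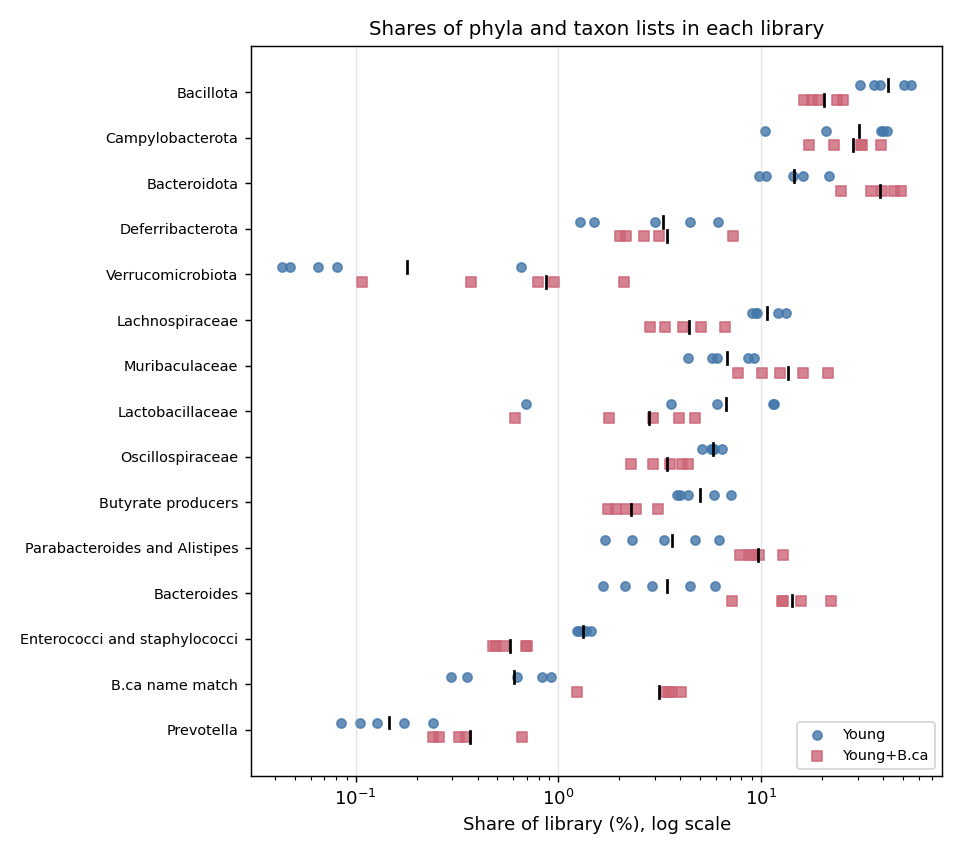
Share of each library, in percent on a log axis, held by 5 phyla and 10 taxon lists. Circles are the 5 Young libraries, squares the 5 Young+B.ca libraries and black bars the group means. For Bacteroidota, Bacteroides and the B.ca name match all squares lie to the right of all circles, and for Bacillota, Lachnospiraceae, Oscillospiraceae and Butyrate producers all squares lie to the left.

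Several lists of Bacteroidota rose together. The list of Bacteroides and Phocaeicola, genera that ferment complex carbohydrates to acetate, propionate and succinate, rose from 3.43% ± 1.77 (SD, n = 5) to 14.2% ± 5.49 (SD, n = 5), or 4.14 times as much. Phocaeicola vulgatus rose 8.50-fold, from 0.498% ± 0.486 to 3.88% ± 2.97 (log2 fold change 3.09, SE 0.73, adjusted p = 0.0475). Bacteroides faecium rose 6.57-fold, from 0.169% ± 0.0849 to 1.18% ± 0.647 (adjusted p = 0.0423), while Bacteroides xylanisolvens, at 0.570% ± 0.262 and 1.20% ± 0.195, did not pass (adjusted p = 0.0890). The list of Parabacteroides, Alistipes, Odoribacter and Rikenella rose from 3.66% ± 1.83 to 9.65% ± 1.90. In it, Alistipes finegoldii rose 6.24-fold to 1.39% ± 0.607 (log2 fold change 2.64, SE 0.45, adjusted p = 0.0151) and Parabacteroides goldsteinii 8.16-fold to 0.476% ± 0.262 (log2 fold change 3.03, SE 0.55, adjusted p = 0.0206). Parabacteroides distasonis, the most abundant species of that list, had 1.41% ± 1.05 and 2.82% ± 2.20 (adjusted p = 0.330), and Alistipes shahii 0.268% ± 0.114 and 0.724% ± 0.168 (adjusted p = 0.0508). The Prevotella list rose from 0.146% ± 0.0627 to 0.366% ± 0.170. Muribaculaceae, a Bacteroidota family of the mouse gut, had 6.81% ± 2.08 and 13.6% ± 5.36 and did not pass (exact p = 0.0317, adjusted p = 0.0603). Within it, Duncaniella sp B8 had 1.30% ± 0.723 and 3.85% ± 1.45 (adjusted p = 0.0755), Muribaculum gordoncarteri 1.11% ± 0.435 and 2.85% ± 1.66 (adjusted p = 0.165), and Duncaniella dubosii 2.02% ± 0.752 and 2.22% ± 0.996 (adjusted p = 0.881). The exact permutation test gave an adjusted p of 0.0215 for the Bacteroides list and for the Parabacteroides and Alistipes list, and 0.0377 for Prevotella.

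Among the members of these lists, 11 of 36 tested Bacteroides and Phocaeicola species were higher and none was lower, against 30 higher when adjusted over the list alone. For Parabacteroides and Alistipes, 6 of 19 species were higher, against 12 when adjusted over the list alone. For Prevotella, 1 of 24 species was higher, against 21 when adjusted over the list alone, and its most abundant members, Paraprevotella xylaniphila, Prevotella dentalis and Prevotella denticola, had adjusted p-values of 0.471, 0.0794 and 0.0595. For Muribaculaceae, 1 of 7 species was higher, against 5 when adjusted over the list alone. A competitive set test with a preset correlation called these 4 lists. All 4 calls were lost when the correlation was estimated: adjusted p = 0.234 with an estimated correlation for Bacteroides and for Parabacteroides and Alistipes, 0.241 for Prevotella and 0.253 for Muribaculaceae. The Prevotella share lost its call without Young 1, 2, 3 or 4 or Young+B.ca 1 (adjusted exact p from 0.0565 to 0.0942), and that of Muribaculaceae passed without Young+B.ca 3, at a difference of 8.21 percentage points (adjusted exact p = 0.0168), and in the total without Helicobacter, at 8.47 percentage points (adjusted exact p = 0.0429).

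Of the lists of Bacillota, 4 fell. Lachnospiraceae, a family of gut clostridia, went from 10.7% ± 1.90 (SD, n = 5) to 4.40% ± 1.49 (SD, n = 5), so that the Young share was 2.43 times the Young+B.ca share. Blautia coccoides, an acetate producer, fell from 3.10% ± 0.812 to 1.09% ± 0.477 (log2 fold change -1.58, SE 0.36, adjusted p = 0.0427). Enterocloster bolteae, at 2.76% ± 0.411 and 1.32% ± 0.480, and Enterocloster clostridioformis, at 0.575% ± 0.182 and 0.221% ± 0.0670, did not pass (adjusted p = 0.0827 and 0.0518). The list of genera with butyrate producers fell from 5.02% ± 1.40 to 2.28% ± 0.529. Its most abundant members, Roseburia intestinalis (0.955% ± 0.643 and 0.301% ± 0.0611), Faecalibacterium prausnitzii (0.538% ± 0.0397 and 0.309% ± 0.0599) and Roseburia hominis (0.545% ± 0.147 and 0.239% ± 0.0827), had adjusted p-values of 0.0860, 0.107 and 0.0713, although no Young+B.ca library reached the lowest Young library in any of the 3. Butyrivibrio crossotus fell from 0.161% ± 0.0873 to 0.0391% ± 0.00708 (log2 fold change -1.92, SE 0.37, adjusted p = 0.0257). The Oscillospiraceae list, made of Acutalibacter, Flavonifractor, Lawsonibacter, Oscillibacter, Ruminococcus and Anaerotruncus, fell from 5.78% ± 0.459 to 3.45% ± 0.861, with 1.51 of the 2.33 percentage points in Acutalibacter muris. In that list, Acutalibacter muris had 2.97% ± 0.234 and 1.46% ± 0.405 (adjusted p = 0.0713), Flavonifractor plautii 1.17% ± 0.184 and 0.881% ± 0.246 (adjusted p = 0.428), and Lawsonibacter asaccharolyticus 0.613% ± 0.0818 and 0.511% ± 0.199 (adjusted p = 0.580). Enterococci, staphylococci and streptococci fell from 1.33% ± 0.0868 to 0.580% ± 0.109. Enterococcus faecalis fell from 0.743% ± 0.135 to 0.296% ± 0.0997 (log2 fold change -1.37, SE 0.32, adjusted p = 0.0460) and Streptococcus gallolyticus from 0.0952% ± 0.0385 to 0.0254% ± 0.00826 (adjusted p = 0.0270), while Enterococcus faecium had 0.159% ± 0.0287 and 0.0765% ± 0.0210 (adjusted p = 0.0729). In all 4 lists every Young+B.ca library lay below every Young library (exact permutation p = 0.00794, adjusted p = 0.0215).

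By species, 4 of 23 species of the Lachnospiraceae list were lower, against 22 when adjusted over the list alone, and 5 of 34 members of the butyrate list were lower, against 25 when adjusted over the list alone. None of 11 species of the Oscillospiraceae list passed, against 4 lower when adjusted over the list alone, and Dysosmobacter, a genus of clostridia outside the list, had 0.804% ± 0.150 and 0.708% ± 0.188 (adjusted p = 0.477 among genera of at least 0.01% tested alone). Of 109 enterococci, staphylococci and streptococci, 7 were lower and 1 was higher, against 18 lower and 1 higher when adjusted over the list alone. The set test with a preset correlation called these 4 lists lower. With the correlation estimated, the calls were lost, with adjusted p = 0.234 with an estimated correlation for Lachnospiraceae, for the butyrate list and for the cocci, and 0.339 for Oscillospiraceae. The calls of Blautia coccoides and Enterococcus faecalis were each lost on leaving out any 1 of 9 libraries, with adjusted p up to 0.0998 and 0.103, and their log2 fold changes lay between -1.80 and -1.41 and between -1.51 and -1.24.

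Lactobacillaceae, lactic acid bacteria, had 6.70% ± 4.83 (SD, n = 5) in Young and 2.80% ± 1.65 (SD, n = 5) in Young+B.ca and did not pass (exact p = 0.159, adjusted p = 0.211). Limosilactobacillus reuteri had 1.47% ± 1.10 and 1.13% ± 0.770, Lactobacillus taiwanensis 2.10% ± 1.85 and 0.468% ± 0.379, and Ligilactobacillus murinus 1.49% ± 1.64 and 0.671% ± 0.655, with adjusted p-values of 0.975, 0.315 and 0.584. One of 69 tested Lactobacillaceae species was higher, 1 also when adjusted over the list alone, and their median log2 fold change was -0.576. Of the 9 members of at least 0.01%, tested with the other such species alone, 0 were higher and 1 was lower. The list's preset call as lower was lost with adjusted p = 0.345 with an estimated correlation. Segmented filamentous bacteria, clostridia that attach to the ileal epithelium, had 0.0518% ± 0.0550 and 0.00985% ± 0.0108 (exact p = 0.0317, adjusted p = 0.0603). None of their 3 names passed, against 2 lower when adjusted over the list alone. Candidatus Arthromitus sp SFB-mouse passed as lower among species of at least 0.01% tested alone (adjusted p = 0.0366), as did the genus among genera of at least 0.01% (log2 fold change -2.43, adjusted p = 0.00999), and the share of all 3 passed in the total without Helicobacter (difference -0.0673 percentage points, adjusted exact p = 0.0429). Akkermansia, a mucin degrader, had 0.179% ± 0.268 and 0.866% ± 0.768 (exact p = 0.0556, adjusted p = 0.0960), and its share passed without Young+B.ca 3 (adjusted exact p = 0.0452). Akkermansia muciniphila had 0.175% ± 0.267 and 0.862% ± 0.768 (adjusted p = 0.147), and none of 4 Akkermansia names passed, also when adjusted over the list alone. Akkermansia muciniphila passed among species of at least 0.01% tested alone (adjusted p = 0.0249). The list of Helicobacter and Campylobacter had 30.5% ± 14.1 and 28.4% ± 8.50 (exact p = 0.738), with Helicobacter typhlonius at 26.0% ± 13.3 and 26.4% ± 8.10 (adjusted p = 0.843) and Helicobacter hepaticus at 3.08% ± 3.51 and 1.30% ± 1.95 (adjusted p = 0.321). One of 67 Helicobacter and Campylobacter species was higher and 1 lower, also when adjusted over the list alone, and their median log2 fold change was -1.19. Of the 13 members of at least 0.01%, tested with the other such species alone, 0 were higher and 2 were lower. The preset call as lower was lost with adjusted p = 0.423 with an estimated correlation. Campylobacter had 0.316% ± 0.213 and 0.141% ± 0.0694 and passed as lower among genera of at least 0.01% tested alone (adjusted p = 0.0431).

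Bifidobacterium had 0.0814% ± 0.00624 (SD, n = 5) and 0.174% ± 0.108 (SD, n = 5, exact p = 0.167), and 1 of 27 species was lower, also when adjusted over the list alone. Its most abundant member, Bifidobacterium pseudolongum, had 0.00840% ± 0.00441 and 0.125% ± 0.113, which did not pass among all species (adjusted p = 0.188) and passed as higher among species of at least 0.01% tested alone (adjusted p = 0.0382), where Bifidobacterium breve passed as lower (log2 fold change -1.43, adjusted p = 0.0220). The list of sulfate reducers, here Desulfovibrio and Desulfomicrobium without Desulfobulbus, had 0.108% ± 0.0215 and 0.226% ± 0.130 (exact p = 0.143), and their preset call was lost with adjusted p = 0.468 with an estimated correlation. The Erysipelotrichia list, here Faecalibaculum, Turicibacter and Allobaculum, had 0.0340% ± 0.00953 and 0.195% ± 0.244 (exact p = 0.167). [Clostridium] innocuum, a member of that class outside the list and named after its values were seen, fell from 1.19% ± 0.286 to 0.484% ± 0.124 (adjusted p = 0.0439). Enterobacteriaceae had 0.401% ± 0.0712 and 0.399% ± 0.0673 (exact p = 0.952), with Escherichia coli at 0.125% ± 0.0617 and 0.195% ± 0.0386 (adjusted p = 0.281). Fungi had 0.00381% ± 0.00211 and 0.00258% ± 0.000706 (exact p = 0.270). No species of these last 4 lists passed, and none did when adjusted over the list alone. Genera often met as reagent contaminants held 0.376% ± 0.0752 and 0.348% ± 0.0424 (exact p = 0.524). Of 226 such species, 5 were higher and 3 lower, against 4 higher and 3 lower when adjusted over the list alone, and the preset call was lost with adjusted p = 0.468 with an estimated correlation.

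Across all species tested, 208 of 5708 changed, 109 higher and 99 lower in Young+B.ca, and 1252 had an unadjusted p under 0.05. Of the 208, 45 had a mean share of at least 0.01%. The 21 of these that rose were all Bacteroidota, with 10 Bacteroides, 3 Alistipes and 3 Parabacteroides species and 1 species each of Phocaeicola, Barnesiella, Duncaniella, Segatella and Tannerella. The strongest rises were those of Parabacteroides chongii (11.7-fold, from 0.0123% ± 0.00760 to 0.146% ± 0.0995, adjusted p = 0.0235), Phocaeicola vulgatus and Parabacteroides goldsteinii. Parabacteroides faecis, Bacteroides sp D2, Bacteroides sp DH3716P and Bacteroides luhongzhouii rose 6.69-fold, 6.26-fold, 6.25-fold and 5.32-fold (adjusted p = 0.0340, 0.0423, 0.0252 and 0.0340). Names of the same genus may share reads, so these need not be separate rises. The 24 that fell were led by Desulfobulbus oralis, the name of an oral sulfate reducer, from 0.0323% ± 0.0190 to 0.00400% ± 0.00140 (log2 fold change -2.89, SE 0.44, adjusted p = 0.00683). Streptococcus pyogenes (log2 fold change -2.14, adjusted p = 0.0397), Clostridium beijerinckii (-1.88, adjusted p = 0.0124), Coprococcus sp ART55/1 (-1.83, adjusted p = 0.0361) and Lachnoanaerobaculum gingivalis (-1.74, adjusted p = 0.0376) followed. Between them ranked Butyrivibrio crossotus (-1.92) and Streptococcus gallolyticus (-1.88), described above. Chakrabartyella piscis (-1.66), Petroclostridium sp X23 (-1.62) and Allocoprobacillus halotolerans (-1.59) fell with adjusted p-values of 0.0397, 0.0490 and 0.0409. Of the 10 largest falls, all but that of Clostridium beijerinckii had their highest share in Young 5. Whether these names stand for separate species or for shared reads was not tested. Among the 312 species of at least 0.01% that were tested, 128 (41.0%) had no overlap between the groups, against 494 (8.65%) of all 5708 tested, where chance gives 0.794%. When all 314 species of at least 0.01% were tested alone, 209 passed, 73 higher and 136 lower. Species named above as not passing that passed there included Roseburia intestinalis, Faecalibacterium prausnitzii and Roseburia hominis (adjusted p = 0.00757, 0.00504 and 0.00460), Enterocloster bolteae, Enterocloster clostridioformis and Acutalibacter muris (0.00559, 0.00349 and 0.00411), and Enterococcus faecium (0.00426), all lower. Bacteroides xylanisolvens, Alistipes shahii, Duncaniella sp B8 and Muribaculum gordoncarteri passed as higher (0.00661, 0.00355, 0.00652 and 0.0233), as did Prevotella dentalis and Prevotella denticola (0.00589 and 0.00462). Parabacteroides distasonis, Duncaniella dubosii, Helicobacter typhlonius and Helicobacter hepaticus did not pass there either (0.111, 0.756, 0.696 and 0.111).

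The count of changed species fell by over 1.5 times without Young 1 (68), Young 3 (103), Young 5 (134), Young+B.ca 1 (61), Young+B.ca 2 (68), Young+B.ca 4 (92) or Young+B.ca 5 (71). The split moved from 109 higher and 99 lower to 123 and 41 without Young 4, and to 94 and 40 without Young 5. Of the 20 species named for the largest rises and falls, Alistipes finegoldii, Clostridium beijerinckii and Desulfobulbus oralis passed without any 1 library, and the adjusted p of the others reached up to 0.113 without 1 library.

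**Figure D2:**
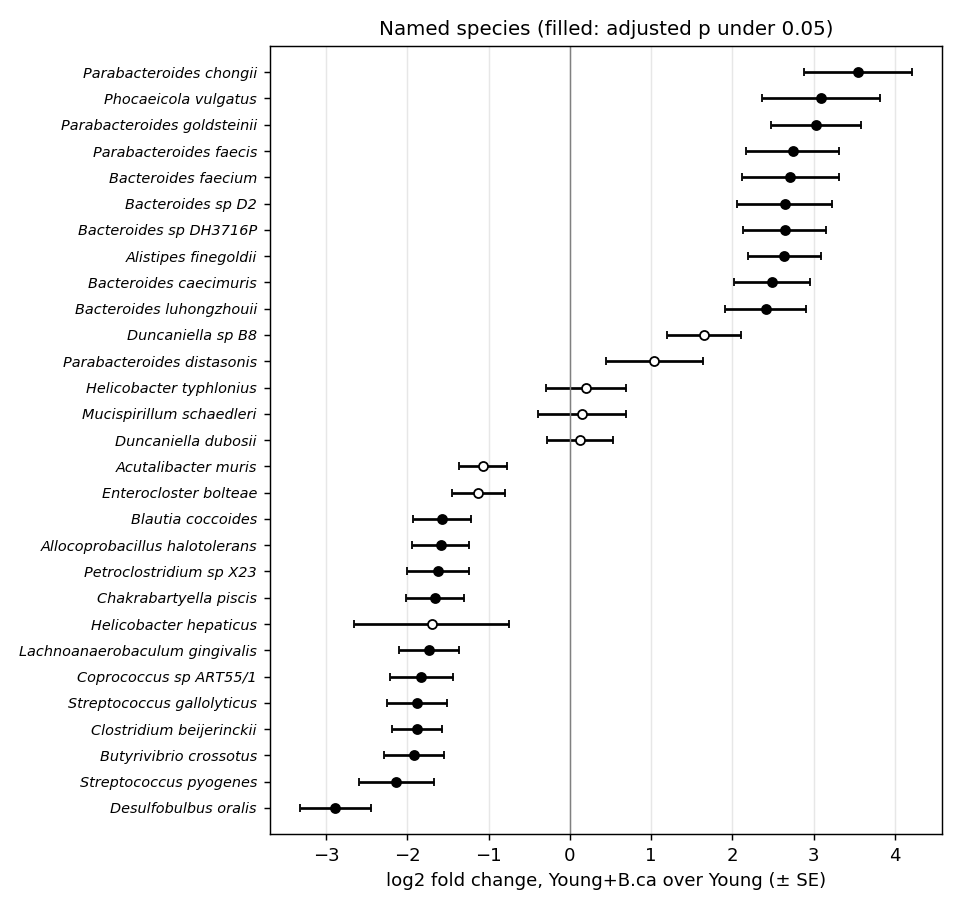
log2 fold change of each named abundant, rising or falling species, Young+B.ca over Young, with bars of 1 standard error. Filled points passed an adjusted p of 0.05 and open points did not. Bacteroidota lie on the right, up to 3.55 for Parabacteroides chongii, and Desulfobulbus oralis lies farthest left at -2.89.

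Summed to genera, 119 of 1947 changed, 37 higher and 82 lower. Phocaeicola rose from 0.665% ± 0.586 (SD, n = 5) to 4.21% ± 2.98 (SD, n = 5), a log2 fold change of 2.76 (SE 0.64, adjusted p = 0.0323). Bacteroides rose from 2.76% ± 1.24 to 9.96% ± 2.79 (log2 fold change 1.92, SE 0.36) and Alistipes from 1.41% ± 0.705 to 4.86% ± 1.41 (1.87, SE 0.36), both with adjusted p = 0.0198. Segatella and Coprobacter, scarcer Bacteroidota, rose 3.67-fold each (adjusted p = 0.0297 and 0.0249). Blautia fell from 5.63% ± 1.09 to 2.02% ± 0.792 (log2 fold change -1.54, SE 0.29, adjusted p = 0.0198). Desulfobulbus (-1.71), Chakrabartyella (-1.66) and Lachnoanaerobaculum (-1.61), each with adjusted p = 0.0198, and Petroclostridium (-1.62, adjusted p = 0.0297) and Allocoprobacillus (-1.59, adjusted p = 0.0198) had the largest falls among genera of at least 0.01% past the threshold. Duncaniella had 3.57% ± 1.05 and 7.33% ± 2.63 (adjusted p = 0.0888), Helicobacter 30.2% ± 14.0 and 28.2% ± 8.46 (adjusted p = 0.980) and Mucispirillum 3.27% ± 2.04 and 3.45% ± 2.19 (adjusted p = 0.887). The count of changed genera fell by over 1.5 times without Young 1 (50), Young 3 (58), Young 4 (70), Young 5 (65), Young+B.ca 1 (42), Young+B.ca 2 (13), Young+B.ca 4 (29) or Young+B.ca 5 (36), and the split became 35 higher and 35 lower without Young 4 and 30 and 35 without Young 5. Each call of a named genus was lost on leaving out 1 library, for Phocaeicola with any of 8 libraries, Segatella 7, Coprobacter 5, Petroclostridium 4, Lachnoanaerobaculum, Chakrabartyella and Allocoprobacillus 3, Bacteroides and Blautia 2, and Alistipes and Desulfobulbus 1 (adjusted p up to 0.0767).

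The 2 groups separated as whole communities. The mean Bray-Curtis dissimilarity, which is 0 for identical and 1 for disjoint communities, was 0.379 between groups, 0.283 within Young and 0.266 within Young+B.ca. Group membership accounted for 0.402 of the summed squared distances (pseudo-F = 5.38, exact permutation p = 0.00794). Bacteroidota and Bacillota had the largest differences in share between the groups, while Helicobacter typhlonius varied widely inside each of them. Shannon diversity was 4.37 ± 0.562 (SD, n = 5) in Young and 4.23 ± 0.222 (SD, n = 5) in Young+B.ca (exact permutation p = 0.611). Without Helicobacter, a setting chosen after the data were seen, it was 5.22 ± 0.101 and 4.99 ± 0.209 (exact permutation p = 0.0556). There, 4 Young+B.ca libraries lay below every Young library. The number of species listed was 5055 ± 789 in Young and 5766 ± 219 in Young+B.ca (exact permutation p = 0.0714). With 1 lowest share for all libraries, that difference turned to -60.6 species (exact p = 0.841), and with species of at least 0.001% it was -307 (exact p = 0.206). It passed without Young 4, at 914.65 species (exact p = 0.0238). The difference in Shannon diversity turned to 0.0353 without Young 5 (exact p = 0.881).

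**Figure D3:**
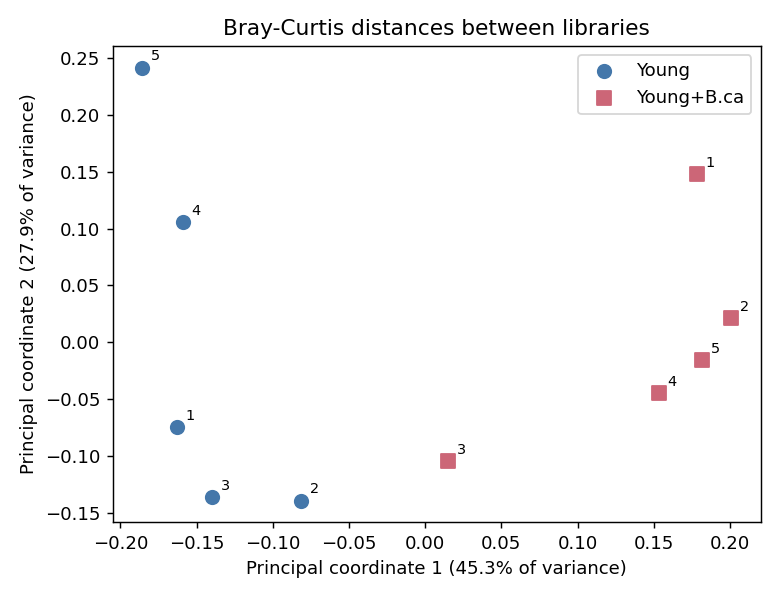
Principal coordinates of the Bray-Curtis dissimilarities between the 10 libraries, with axes holding 45.3% and 27.9% of the variance. Circles are Young and squares Young+B.ca libraries, numbered by replicate. Mean dissimilarity was 0.379 between groups, against 0.283 and 0.266 within them.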

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

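The test for reads of 1 Bacteroides species behind the other Bacteroidota genera, and that of the smallest listed share behind the number of species, were chosen after the results were seen. Single libraries stood far from the other 4 of their group in 31 of 236 sets of 5 values (13.1%). The bound used gives about 5% by chance for normally distributed values. Shares in percent need not be normal, and most flags were on the high side, so the excess alone does not mark libraries as odd. Many of these sets overlap, since a species, its genus, its phylum and its list share values. Young+B.ca 5 held 7 of the 31, Young 1, Young 5 and Young+B.ca 3 held 5 each, Young+B.ca 1 and Young+B.ca 2 held 3 each, Young 2 held 2 and Young+B.ca 4 held 1.

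Bacteroides caecimuris was low in Young+B.ca 3, at 1.116% against 3.12% to 3.72% in the other Young+B.ca libraries, and so was the sum of the B.ca name matches, at 1.229% against 3.37% to 4.04%. Both values still lay above all Young libraries. In the same library Roseburia hominis was high at 0.3821%, Streptococcus pyogenes at 0.01274% and Candidatus Arthromitus sp SFB-rat-Yit at 0.003739%. In Young+B.ca 5, Mucispirillum schaedleri, and with it the genus Mucispirillum and the phylum Deferribacterota, reached 7.282% against 2.02% to 3.15% in the others. Helicobacter hepaticus, a bacterium that can inflame the liver and bowel of susceptible mice, reached 4.765% there against 0.149% to 0.732%, Faecalibaculum rodentium 0.5853%, the Erysipelotrichia list 0.612% and Candida albicans 0.001263%. In Young+B.ca 1 the Prevotella list reached 0.6594%, Paraprevotella xylaniphila 0.0435% and segmented filamentous bacteria 0.02862%. In Young+B.ca 2, Lawsonibacter asaccharolyticus reached 0.8572%, Klebsiella pneumoniae 0.09521% and Salmonella enterica 0.1081%, and in Young+B.ca 4 Parabacteroides distasonis reached 6.682% against 1.44% to 2.56%.

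Among the Young libraries, Helicobacter hepaticus reached 9.257% in Young 1 against 0.648% to 2.25% in the others, and Helicobacter winghamensis 0.6559%. Segmented filamentous bacteria reached 0.1479% in Young 1, with Candidatus Arthromitus sp SFB-mouse at 0.0941% and Candidatus Arthromitus sp SFB-mouse-NL at 0.05135%. In Young 5, Akkermansia, which is also the phylum Verrucomicrobiota here, reached 0.6577% against 0.0435% to 0.0806% in the others, with Akkermansia muciniphila at 0.6521%. Phocaeicola vulgatus reached 1.333% in Young 5 and Lachnoanaerobaculum 0.1888%. In Young 2, Muribaculum gordoncarteri reached 1.879% and Desulfovibrio fairfieldensis 0.05088%.

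Bacteroidota genera were higher together in Young+B.ca. In the total without Bacillota, the Bacteroidota share was 26.7% ± 13.3 (SD, n = 5) in Young and 48.7% ± 12.0 (SD, n = 5) in Young+B.ca. It was still 22.1 percentage points higher (unadjusted exact p = 0.0397), though the groups overlapped. This argues only weakly against room left by the lower Bacillota as the whole cause. The sum of 13 Bacteroidota genera outside Bacteroides and Phocaeicola was 13.5 percentage points higher (exact p = 0.00794). Reads of 1 Bacteroides species given to them would also produce this. Their log2 ratio to Bacteroides caecimuris had a median SD within groups of 0.596, with a bootstrap interval of the median from 0.503 to 0.642. The SD was over 0.5 in 10 of the 13 genera and under 0.2 in 0. The ratio was therefore not fixed, which argues against reads of Bacteroides caecimuris as the whole share of these genera. Such reads as part of the rise stay open. Within Bacteroides and Phocaeicola, reads of Bacteroides caecimuris given to 34 other species could not be settled: the log2 ratio to it had a median SD within groups of 0.594, with a bootstrap interval of the median from 0.464 to 0.810, where a fixed ratio asked for under 0.2 and separate species for over 0.5. What Young+B.ca stands for in the labels stays open as a biological explanation and was not tested, and cage or batch is not given.

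The Bacillota lists that passed were lower together in Young+B.ca. By the exact test, Lactobacillaceae and segmented filamentous bacteria did not pass (adjusted p = 0.211 and 0.0603). The Erysipelotrichia list had a higher mean in Young+B.ca and did not pass either (adjusted p = 0.211). In the total without Bacteroidota, the Bacillota share was 50.0% ± 14.3 (SD, n = 5) in Young and 34.0% ± 7.93 (SD, n = 5) in Young+B.ca, a difference of -16.0 percentage points (exact p = 0.0635). That is 73.1% of the difference in the full total, so dilution by Bacteroidota and a loss of Bacillota cannot be told apart with this spread between libraries. A few source genomes split over many names stay open too, since the log2 ratios between 12 called members had a median SD within groups of 0.416 over 66 pairs, between the 0.2 and 0.5 set as bounds. What Young+B.ca stands for stays open and untested as a biological explanation.

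More species were listed in Young+B.ca than in Young, 5766 ± 219 against 5055 ± 789. With 1 lowest share of 0.000446% for all libraries the difference was -60.6 species (exact p = 0.841), which is consistent with the lower smallest share listed in the Young+B.ca libraries as its source. What remained above that floor was smaller than the spread between libraries, and no biological explanation was tested.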

How the results depend on the processing

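The trend in limma, the single lowest share, the total without Helicobacter and the centring over species of at least 0.01% were chosen after seeing the data. The 208 changed species became 103 with species above 0 in at least 2 libraries, 99 with a pseudocount 10 times smaller, 440 with the trend and 472 with 1 lowest share for all libraries (158 higher, 314 lower). They were 232 with the centred log ratio and ranged from 61 to 182 with 1 library left out, with fewer libraries in the fit. Genera went from 119 to 185 with the trend and 189 with 1 lowest share, were 159 with the centred log ratio (64 higher, 95 lower), and from 13 to 127 with 1 library left out. The median log2 fold change of species of at least 0.01% was -0.67, and -0.50 when centred on these species. With 1 library left out, 0 phylum shares passed in each case, and 7 to 10 list shares passed, as did 10 in the total without Helicobacter. The difference in Shannon diversity lay between -0.263 and 0.0353, the latter without Young 5, and that in species listed between 411.65 and 914.65, the latter passing without Young 4. It was -307.2 with species of at least 0.001% and -60.6 with 1 lowest share. For these the cause was not tested. Over 116 single lists, phyla, genera and species, 1683 of 2043 comparisons kept their side of the threshold, 285 lost their call and 75 came to pass. Where the main fit or the alternative passed, 0 changed direction. Changes of direction among results that passed in neither were counted as kept. With 1 library left out, the log2 fold change of Helicobacter typhlonius lay between -0.206 and 0.391. The difference in the Campylobacterota share lay between -7.18 and 0.639 percentage points. Depth is unknown, and values near the smallest listed share are the least certain. Alternatives for counts (other count tests, total-sum scaling, Chao1, thinning) were not run on fractions.

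The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.0674, 0.0558, 0.00644, -0.0706 and 0.0304, and 2 of 10 libraries correlated best with their own number. With the replicate block, 64 species and 15 genera passed, and 0 phylum and 0 list shares, since 0.0625 is the smallest p of paired sign flips. The difference in the B.ca name match stayed at 2.55 percentage points and the group term at 0.402, each with exact p = 0.0625.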

Other observations

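The tests of single genera given here were read after their values were seen. Among 267 genera with a mean share of at least 0.01%, tested alone with limma, 117 passed, 22 higher and 95 lower. Butyricimonas, a Bacteroidota genus that makes butyrate, had 0.258% ± 0.120 (SD, n = 5) in Young and 0.643% ± 0.231 (SD, n = 5) in Young+B.ca, a log2 fold change of 1.38 (SE 0.36, adjusted p = 0.00824). It moved against the butyrate list, which holds only clostridia and fell. Muribaculum had 1.54% ± 0.432 and 4.39% ± 2.51 (log2 fold change 1.36, adjusted p = 0.00822), Barnesiella 0.0204% ± 0.00389 and 0.0587% ± 0.0117 (1.52, adjusted p = 0.00186), Sodaliphilus 0.0426% ± 0.0159 and 0.112% ± 0.0465 (1.38, adjusted p = 0.00620) and Akkermansia a log2 fold change of 2.62 (SE 0.82, adjusted p = 0.0211). Centring on the mean log share of these genera moved the split from 22 higher and 95 lower to 42 higher and 65 lower.

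The groups stayed separate without the species whose names fit B.ca. These held only 0.604% of the Young and 3.15% of the Young+B.ca libraries, so leaving them out could change the distances little. Without those 9 species the group term still held 0.384 of the squared Bray-Curtis distances, and without the 38 Bacteroides and Phocaeicola species it held 0.344 (exact permutation p = 0.00794 for each, the smallest possible). Bacteroides caecimuris was not the species with the strongest rise either. Its log2 fold change ranked 14 among 312 tested species of at least 0.01%, behind Parabacteroides chongii, Phocaeicola vulgatus and Parabacteroides goldsteinii among others. That rank counts species that did not pass, such as Bifidobacterium pseudolongum, Akkermansia muciniphila and Faecalibaculum rodentium (adjusted p = 0.188, 0.147 and 0.234 in limma). Bacteroides caecimuris was among the 10 largest rises of species past the threshold.

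Both counts of calls were compared with those of 99 other splits of the libraries into 2 groups of 5. The real split called 208 species and the highest of the other 99 splits called 13. For genera, the real split called 119 and the highest other split 5. With the real split counted among the 100, 1 of 100 is the smallest share possible. These splits treat the libraries as independent, so a cage or batch shared within a group could also give such counts. Among the 314 species of at least 0.01% tested alone, the real split called 209 and the highest other 75.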
